A study of Mus musculus with 6 samples.

How the data were processed

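The data are from ribosome-bound RNA of cerebellar Purkinje neurons, in 6 libraries of 1 cerebellum each, 3 control and 3 cKO. Per the labels' protocols, each cerebellum was homogenised in 1.5 mL, and 60 µg of each of 2 anti-GFP antibodies was used per immunoprecipitation. Double-stranded cDNA was made and amplified from 10 ng of RNA with the NuGEN Ovation system, which primes at poly(A) tails and at random positions, and 2 µg was sheared for a TruSeq DNA library with inserts of 400 bp, sequenced on an Illumina HiSeq instrument. Amplification from 10 ng means that reads are not independent molecules, so intervals and floors cover counting error only. Per the submitters' processing notes, TopHat2 2.1.0, HTSeq 0.6.0 and the mouse build mm10 were used. The annotation and strand setting used for counting, and the handling of reads with several alignments, are not given in the sources used here, so genes that overlap, lie antisense to another gene or have near-identical copies are uncertain.

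The authors deposited raw read counts per gene for the 6 libraries in 1 table of 23420 rows, with no normalization. In it 27 rows had gene names that a spreadsheet had turned into dates and 4 rows carried a repeated name. The authors also deposited a list of splice junctions for each library, made by TopHat per the file headers, in which the count is the number of reads that span the junction. Gene counts summed to between 140110897 and 160571518 per library. The ribosomal RNA precursor row Rn45s took 9.56% to 13.5% of them.

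Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, and a quasi-likelihood test of cKO against control with no other covariate. Adjusted p values are Benjamini-Hochberg values over the 16067 genes tested, and 0.05 was the threshold. Standard errors were taken from the log2 fold change and its F statistic. Levels are CPM on TMM-scaled library sizes. Before the data were examined, 24 gene lists with 577 distinct symbols were fixed, among them markers of the other cell types of the cerebellum. Symbols were matched to the table, 7 of them through an older symbol in the reference. Lists were tested with camera (limma 3.58.1) on log CPM with a prior count of 3 and a preset correlation of 0.01, and adjusted over the 24 lists. Camera with an estimated correlation and fry were run beside it.

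Junction coordinates are 1-based first and last bases of the intron in mm10. Junctions were compared with the introns of the GENCODE annotation of the same build, in which between 97.9% and 98.5% of junction reads per library fell on annotated introns. Junctions with at least 10 reads over the 6 libraries and reads in at least 2 were joined into clusters that share a donor or an acceptor. Each junction was tested against the rest of its cluster with edgeR's diffSpliceDGE, and a call needed a change in cluster share of at least 5 percentage points. A rare junction had a mean share under 5% in the reference group, counted the same way in both directions. Rare junctions used for comparison were those under 5% over the pooled 6 libraries. Exon inclusion is the mean of the reads of both inclusion junctions divided by that mean plus the reads of the skipping junction. A new exon was a pair of raised rare junctions that share the donor and the acceptor of the leading junction and enclose at most 500 bp. Its junctions could be annotated or not, so new refers to use in cKO and not to the annotation.

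The gene and junction tests were first tested on simulated data. With 200 genes changed, drawn from the means and library sizes of these libraries, 36% of genes changed 1.5-fold, 66% of those changed 2-fold, 78% of those changed 4-fold and 88% of those changed 8-fold were recovered among 15873 genes, and 4.97% of calls were false. Junctions raised to a share of 10%, 20% and 40% were recovered in 86.2%, 96.9% and 100% of cases among 106133 junctions, and 3.63% of calls were false. The raised junctions lay only in clusters with a mean above 100 reads per library. The same dispersion was set for every junction, and any call in a changed cluster counted as true. These values therefore do not describe calls in smaller clusters.

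The genes named are Rbm17, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap and whose higher group has a mean of at least 50 counts, and from each list up to 4 called members with the smallest p, or 2 members with the highest level where none was called. Some genes that this rule takes are not named here. The junctions named are the 10 largest rises and the 5 largest falls of rare junctions with at least 10 reads in every library of the higher group, 1 per gene. Any other gene or junction named was chosen after its values were seen. The alternatives tried were other scalings (RLE, upper quartile), other count filters (none, or at least 50 counts in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, other junction clusters, read minimums and share changes, and, chosen after seeing the data, removal of the Rn45s and Lars2 rows, thinning of junction reads and narrower sets of rare junctions. Splice site sequences were not analysed here.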

Results

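Ribosome-bound RNA was purified from cerebellar Purkinje neurons of 4-week-old C57BL/6 mice by BacTRAP, in which a GFP-tagged ribosomal protein driven by the Purkinje gene Pcp2 is pulled down with its bound RNA. RBM17 is a splicing factor that takes part in 3' splice site recognition. The study compared 3 control libraries, which carried a floxed and a wild-type Rbm17 allele and no Cre, with 3 conditional knockout (cKO) libraries, which carried Pcp2-Cre, a floxed and a null Rbm17 allele. The series title names loss of RBM17 and extensive cryptic splicing, so the comparison asks which transcripts and which splice junctions differ when Rbm17 is deleted in these neurons. Cre and the null allele were present only in cKO, so each difference below is one between these whole genotypes. Gene counts summed to 141035957, 149552228 and 140110897 in the control libraries and to 147836723, 145234116 and 160571518 in the cKO libraries. Spliced reads over junctions numbered 74362168, 78104343 and 73796963 in control and 80988391, 73457422 and 83976095 in cKO. Each pull-down used 1 cerebellum, per the labels' protocols.

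Reads that skip exon 4 of Rbm17 rose in every cKO library. These reads tell neither the null allele from the floxed allele nor Purkinje cells from other cells in the pull-down. How far Cre deleted the floxed allele was therefore not measured. Exon 4 of Rbm17 (mm10 chromosome 2, 11596629 to 11596795, 167 bp, minus strand) was included in 99.6% ± 0.33 (SD, n = 3) of control transcripts and in 53.4% ± 4.1 (SD, n = 3) of cKO transcripts, estimated from junction reads. The junction that joins exon 3 to exon 5 (11595429 to 11598051), which is not an annotated intron, had 3, 1 and 1 reads in control and 137, 106 and 136 reads in cKO. Its share of its junction cluster rose from 0.219% ± 0.17 to 30.5% ± 3.5 (SD, n = 3 each; edgeR junction test, adjusted p = 3.6e-09). At gene level Rbm17 fell from 41.6 ± 0.73 to 25.9 ± 0.36 CPM (SD, n = 3), a log2 fold change of -0.69 (SE 0.09; edgeR quasi-likelihood test, adjusted p = 0.0016). All 3 cKO libraries lay below all 3 control libraries. The junction between exons 2 and 3, upstream of the skipped exon, stood at 7.78 ± 0.44 RPM (scaled to junction reads) in control and 7.34 ± 0.55 in cKO (SD, n = 3). Those of exons 3 and 4 and of exons 4 and 5 fell from 7.08 ± 0.43 to 2.37 ± 0.24 and from 3.36 ± 0.35 to 1.26 ± 0.16. Further downstream, those of exons 10 and 11 and of exons 11 and 12 fell from 12.4 ± 0.15 to 7.79 ± 0.14 and from 15.0 ± 0.63 to 9.06 ± 0.49.

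**Figure D1:**
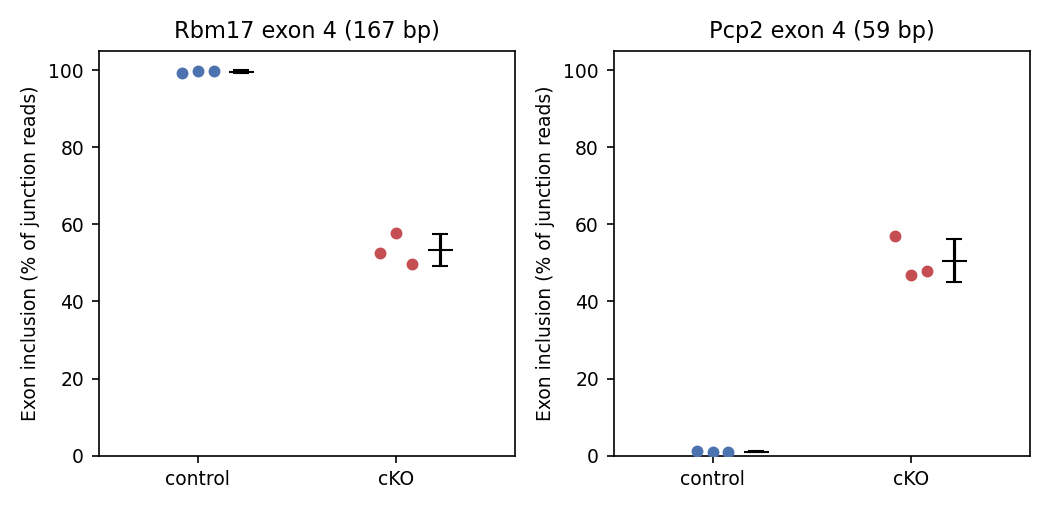
Inclusion of Rbm17 exon 4 and of the Pcp2 cassette exon in each library, as the percent of junction reads that include the exon (vertical axis); points are libraries, the bar and whiskers are the mean and SD of 3. Rbm17 exon 4 lies at 99.6% in control and 53.4% in cKO on average, and the Pcp2 exon at 0.99% and 50.5%.

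Of 16067 genes tested, 647 rose and 618 fell in cKO (edgeR quasi-likelihood test, adjusted p under 0.05). Of 31 Purkinje cell markers 13 fell, while 16 of 26 p53 targets and 11 of 20 microglial markers rose. Camera called these 3 lists with a preset correlation, and their adjusted p was 0.40 to 0.47 with an estimated correlation. Among called genes, 299 had a log2 fold change above 1 and 77 had one below -1. The first principal component held 39.6% of the variance and separated the groups. All 1265 called genes had groups that did not overlap, as did 28.4% of tested genes, where chance gives 10% for 3 against 3. The number called was 548 without control replicate 2, 706 without cKO replicate 1, 795 without cKO replicate 2 and 530 without cKO replicate 3. DESeq2 called 2107 genes, among them 1264 of the 1265.

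p53 target genes held the most called members of the 24 lists. Of 26 members tested, 16 rose and 0 fell (20 rose and 2 fell when adjusted over the list alone), with a mean log2 fold change of 1.00 and quartiles of 0.46 and 1.61, against a mean of 1.34 for microglial markers. Phlda3 rose from 9.85 ± 0.17 to 39.2 ± 3.5 CPM (SD, n = 3; log2 fold change 1.99, SE 0.11, edgeR adjusted p = 1.7e-05). Cdkn1a, the cell cycle inhibitor p21, rose from 70.8 ± 3.3 to 214.2 ± 37 CPM (3.03-fold). Bax, a pro-apoptotic BCL2 family member, rose by 1.31 on the log2 scale, and the nuclease gene Aen by 1.26. The camera test with a preset correlation gave an adjusted p of 2.8e-11 for the list, and adjusted p = 0.40 with an estimated correlation.

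Part of the markers of microglia and macrophages rose, from low levels. Of 20 members tested, 11 rose and 0 fell (13 rose when adjusted over the list alone), with a median log2 fold change of 1.31 (camera adjusted p = 2.7e-08; adjusted p = 0.47 with an estimated correlation). The complement gene C1qc rose from 6.59 ± 0.52 to 16.9 ± 3.8 CPM, the signalling adaptor Tyrobp from 0.781 ± 0.41 to 6.14 ± 2.3, the lysosomal glycoprotein gene Cd68 from 2.60 ± 1.1 to 9.65 ± 1.8 and the Fc receptor subunit gene Fcer1g from 3.61 ± 0.47 to 9.15 ± 2.1 (SD, n = 3 each). The homeostatic microglial genes P2ry12 and Tmem119, singled out after their values were seen, had log2 fold changes of -0.02 (SE 0.21) and -0.10 (SE 0.32). In the interferon response list, 4 of 22 members rose and 0 fell (5 rose when adjusted over the list alone), with a median log2 fold change of 0.99 (camera adjusted p = 8.0e-05; adjusted p = 0.47 with an estimated correlation). Ddx58, which encodes the RNA sensor RIG-I, rose by 1.97 on the log2 scale (SE 0.23), while the calls of Irf9, Oasl2 and Ifit2 were lost in at least 5 of the 6 fits that left out 1 library. Replicate 1 was the highest cKO library in each raised gene named here, with C1qc at 20.8 CPM against 13.2 and 16.6 and Oasl2 at 8.48 against 3.95 and 3.58. In the same libraries 13 of 31 Purkinje cell markers fell (median -0.45).

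Stress and injury genes rose in part. In the list of integrated stress response targets, 6 of 35 members rose and 0 fell (8 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0014; adjusted p = 0.47 with an estimated correlation). Among them the transcription factor genes Ddit3, Atf4 and Atf3 had log2 fold changes of 1.56 (SE 0.17), 0.65 (SE 0.08) and 3.65 (SE 0.56), and Sesn2 one of 1.09 (SE 0.14). In the neuronal injury list, 6 of 19 members rose and 1 fell (7 and 1 when adjusted over the list alone; camera adjusted p = 0.0040; adjusted p = 0.47 with an estimated correlation). The small heat shock protein gene Hspb1 rose from 6.15 ± 0.70 to 54.5 ± 28 CPM, Jun by 0.90 and Tnfrsf12a by 1.69 on the log2 scale. Of the 16 cytosolic heat shock genes, Hspb1 alone was called, also when adjusted over the list alone (camera adjusted p = 0.18). Among 18 immediate early genes 1 rose, Ier5 (log2 fold change 0.84; 1 rose and 1 fell when adjusted over the list alone). The list's median of -0.03 and mean of 0.14 differed in sign, and camera gave an upward direction (adjusted p = 0.76). In the same libraries 11 of 20 microglial markers rose (median 1.31), and cKO replicate 1 stood above the other cKO libraries in several genes of both groups, chosen after their values were seen, with Hspb1 at 85.9 CPM against 31.2 and 46.4, Atf3 at 32.0 against 15.3 and 15.8, and Tyrobp at 8.82 against 4.52 and 5.06. Gfap stood at 171.2 CPM there against 91.1 and 104.1. The call of Ier5 was lost without control replicate 2 or cKO replicate 1.

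Part of the Purkinje cell markers fell. Of 31 Purkinje cell markers, 13 fell and 0 rose (19 fell when adjusted over the list alone), with a median log2 fold change of -0.45 (camera adjusted p = 2.2e-10; adjusted p = 0.47 with an estimated correlation). Pcp2 fell from 1052 ± 43 to 399.0 ± 74 CPM (log2 fold change -1.40, SE 0.13, edgeR adjusted p = 3.5e-04), Car8 from 12479 ± 1956 to 6221 ± 489 and Rgs8 from 7408 ± 979 to 3692 ± 431 (SD, n = 3 each). In the Purkinje calcium signalling list, 14 of 25 members fell and 0 rose (19 fell when adjusted over the list alone; median -0.49; camera adjusted p = 3.0e-10; adjusted p = 0.47 with an estimated correlation). Its calcium pump gene Atp2a2 fell from 1906 ± 267 to 1088 ± 32 CPM (SD, n = 3; log2 fold change -0.81, SE 0.11). In the same libraries 11 of 20 markers of microglia rose, with the median of 1.31 given above.

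Part of the synaptic and channel genes fell. Of 36 glutamate and GABA receptor and scaffold genes, 10 fell and 0 rose (16 fell when adjusted over the list alone; median -0.33; camera adjusted p = 7.9e-09; adjusted p = 0.40 with an estimated correlation). The AMPA receptor subunit genes Gria3 and Gria2 and the GABA-B receptor gene Gabbr2 had log2 fold changes of -1.13 (SE 0.08), -1.02 (SE 0.09) and -0.76 (SE 0.09). Of 26 voltage-gated channel genes, 11 fell and 0 rose (13 fell when adjusted over the list alone; median -0.21; camera adjusted p = 5.9e-08; adjusted p = 0.47 with an estimated correlation). The sodium channel genes Scn1a and Scn8a had log2 fold changes of -0.87 (SE 0.08) and -0.64 (SE 0.09), the calcium channel subunit gene Cacna2d2 one of -0.87 (SE 0.09) and the BK channel gene Kcnma1 one of -1.02 (SE 0.12). Among 27 genes of spinocerebellar ataxias, 6 fell and 1 rose (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0013; adjusted p = 0.47 with an estimated correlation), among them Car8, whose levels stand with the Purkinje cell markers. In the same libraries 13 of 31 Purkinje cell markers fell (median -0.45) and 11 of 20 microglial markers rose (median 1.31).

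Among markers of 5 other cerebellar cell types, 1 gene rose and 3 fell. Of 20 granule cell markers, 0 passed edgeR's test (3 fell at an unadjusted p under 0.05, and 2 by DESeq2), with a median log2 fold change of -0.08 (camera adjusted p = 0.19). The granule cell marker Cbln3 stood at 1718 ± 401 CPM in control (SD, n = 3), above the Purkinje marker Pcp2 at 1052 ± 43. The pull-down thus also held RNA of other cell types, and levels and exon inclusion are those of the mixture. Of 15 interneuron markers, 0 passed edgeR's test (0 at an unadjusted p under 0.05, and 0 by DESeq2; median -0.16; camera adjusted p = 0.30). Of 16 endothelial markers, 0 passed edgeR's test (0 at an unadjusted p under 0.05, and 0 by DESeq2), and their median of -0.04 and mean of 0.05 differed in sign (camera upward, adjusted p = 0.84). Of 20 oligodendrocyte markers, Trf fell (log2 fold change -0.52, SE 0.11), and the list had a median of -0.30 (2 fell when adjusted over the list alone; camera adjusted p = 0.0022; adjusted p = 0.65 with an estimated correlation). Of 19 astrocyte and Bergmann glia markers, Gfap, the intermediate filament gene of reactive astrocytes, rose from 44.4 ± 4.4 to 122.1 ± 43 CPM, whereas Slc4a4 and Hopx fell by 0.36 and 0.32 on the log2 scale (1 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.23). The calls of Trf, Slc4a4 and Hopx were lost in at least 5 of the 6 fits that left out 1 library.

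Splicing factor genes changed in both directions. Among 28 genes of the U2 snRNP and of 3' splice site recognition, 5 rose and 1 fell (8 and 2 when adjusted over the list alone; median 0.13; camera adjusted p = 0.090). Sf3b2, Puf60 and U2af1 had log2 fold changes of 0.57 (SE 0.11), 0.47 (SE 0.11) and 0.59 (SE 0.14), and Rbm39 one of -0.37 (SE 0.08). Among 50 SR protein, hnRNP and splicing kinase genes, 2 rose and 2 fell, among them Cirbp and Son upward and Luc7l downward (2 and 2 also when adjusted over the list alone; camera adjusted p = 0.84). Luc7l had a log2 fold change of -0.61 (SE 0.10). Its call held in each of the 6 fits that left out 1 library, whereas those of Sf3b2, Puf60, U2af1, Rbm39, Cirbp and Son were lost in 2 or more of them. Of 19 genes of nonsense-mediated decay and the exon junction complex, 0 passed edgeR's test (1 rose at an unadjusted p under 0.05, and 1 by DESeq2; median 0.08; camera adjusted p = 0.30).

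The remaining lists held few called genes. Of 20 cholesterol synthesis genes, 0 passed edgeR's test (6 fell at an unadjusted p under 0.05, and 1 by DESeq2), while their median log2 fold change was -0.27 (camera adjusted p = 4.0e-04; adjusted p = 0.62 with an estimated correlation). Of 21 ER chaperone genes, Sdf2l1 fell (log2 fold change -0.88, SE 0.18; 1 fell when adjusted over the list alone; camera adjusted p = 0.024; adjusted p = 0.65 with an estimated correlation). Of 45 oxidative phosphorylation genes, Sdhc rose and Cox7b fell by 0.31 on the log2 scale (1 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.71). Of 35 axon and microtubule genes, 1 rose and 2 fell, among them Stmn1 upward and Nefl downward (2 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.25). The call of Stmn1 was lost without control replicate 2, and those of Sdf2l1, Sdhc, Cox7b and Nefl in 3 or more fits that left out 1 library. Camera with the preset correlation called 13 of the 24 lists, 5 upward and 8 downward. With an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, and fry called 3.

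**Figure D2:**
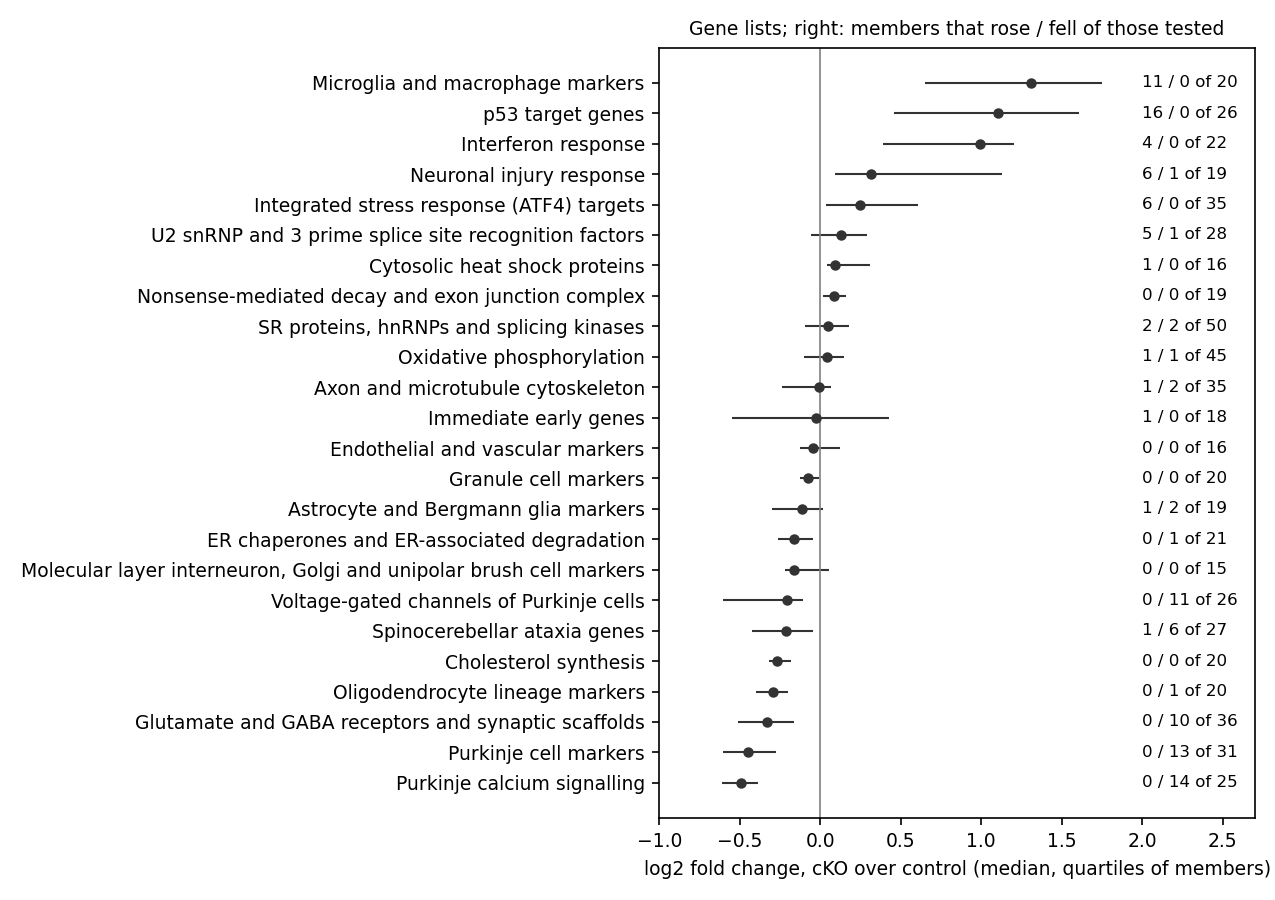
Log2 fold change of cKO over control for the 24 gene lists (horizontal axis); points are medians and whiskers reach the quartiles of the tested members, and the numbers at the right count members that rose and that fell. Medians reach 1.31 for microglial markers and -0.49 for Purkinje calcium signalling.

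The genes with the largest rise were nearly silent in control libraries. Spata31d1a had 0 counts over the 3 control libraries and 236, 68 and 117 counts in cKO, a level of 0.878 ± 0.52 CPM (SD, n = 3) that is at least 121.0-fold higher than the floor of 3 counts over the control group. The brown fat uncoupling protein gene Ucp1 had 0 counts in control and 0.458 ± 0.17 CPM in cKO (at least 63.1-fold higher), and the interferon-induced gene Mx1 had 0 and 0.375 ± 0.11 (at least 51.7-fold higher). Colec10, Gm5077, BC089597 and Mir181a-1 also had 0 control counts, and the calls of Colec10, Gm5077 and Mir181a-1 were lost without cKO replicate 1, that of Colec10 also without control replicate 2. Mmp12, a macrophage metalloelastase, had 1 control count and 675 cKO counts, a ratio of 591 with a 95% counting interval of 106 to 23361. Olfr1392 and Prss38 also had 1 control count each, with ratios of 386 (68.9 to 15275) and 173 (30.7 to 6877). The 10 largest falls were in Opn1mw, BC048943, Atp6v1b1, Ldhd, Tmtc1, Cdca7l, Lingo4, Gm13944, 2610034M16Rik and Acot5. Tmtc1 fell from 135.0 ± 14 to 39.3 ± 0.87 CPM (log2 fold change -1.78, SE 0.10, edgeR adjusted p = 1.7e-05), Lingo4 from 31.4 ± 5.3 to 9.55 ± 1.4 and Ldhd, a D-lactate dehydrogenase gene, from 16.8 ± 0.61 to 4.86 ± 0.28 (SD, n = 3). The calls of Opn1mw and Cdca7l were lost in each of the 6 fits that left out 1 library, and those of Atp6v1b1, Acot5 and 2610034M16Rik in 2 or 3 of them. That of Opn1mw was also lost with the replicate block.

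Junctions of low use in control gained reads in cKO. Of 112047 junctions tested in 29112 clusters, 842 changed, 738 upward and 104 downward (edgeR junction test within the cluster, adjusted p under 0.05 and a share change of at least 5 percentage points). Junctions under 5% of their cluster in control rose in 645 cases, and junctions under 5% in cKO fell in 44. Of those 645 raised rare junctions, 474 were not annotated introns, against 28 of the 44 lowered. Of the 50875 rare junctions that were not raised, 40448 were not annotated introns, a larger share than among the raised ones. The raised junctions lay in 482 annotated genes, and 30 lay in no annotated gene. The count of raised rare junctions was 429 without cKO replicate 1. With limma-voom the balance was less one-sided, with 1148 junctions upward and 1042 downward, and 838 rare junctions raised and 93 lowered. With reads that share the acceptor only, 394 rare junctions rose and 17 fell.

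In the gene Ddx27, an RNA helicase (chromosome 2, 167024558 to 167024790, plus strand), a junction from an annotated donor to an unannotated acceptor had 0 reads in every control library and 57, 41 and 84 reads in cKO. Its share of the cluster was 47.6% ± 18 in cKO (SD, n = 3; edgeR adjusted p = 5.9e-04). In Tenm2, a teneurin adhesion gene (chromosome 11, 36163051 to 36163718), a junction of the same kind rose from 0 reads to a share of 53.3% ± 20. In Prickle2 (chromosome 6, 92407210 to 92410756) the share rose from 0 reads to 45.0% ± 11 (SD, n = 3). Outside annotated genes, a junction on chromosome 13 (22629061 to 22631278) had 0 reads in control and 151, 107 and 108 in cKO (share 45.2% ± 3.4, edgeR adjusted p = 1.9e-08), and one on chromosome 8 (19704305 to 19706688) had 0 reads in control and 79, 71 and 49 in cKO (share 78.4% ± 9.6), a call that was lost without cKO replicate 1. Junctions in 1700095A21Rik and Gspt2 and 3 outside genes, 2 on chromosome 2 and 1 on chromosome 7, completed the 10 largest rises, and the calls of these 5 were lost in 2 or more of the 6 fits that left out 1 library. Zdhhc23 (chromosome 16, 43975746 to 43978907), a palmitoyltransferase gene, held one of the 5 largest falls, from 14, 14 and 29 reads in control to 0 in cKO. The others were in Zfp316 and Zfp930 and outside genes on chromosomes 19 and 15. Of these 5, the chromosome 15 junction (77356660 to 77356874; share 54.5% ± 3.2 to 0 reads) kept its call in each fit that left out 1 library, and the others lost it in 4 or 5. With the replicate block 7 of the 15 named junctions lost their call, those in 1700095A21Rik, Gspt2, Zfp316 and Zfp930, the chromosome 7 and 19 junctions and 1 on chromosome 2 (149575310 to 149577557).

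Raised rare junctions most often kept the main donor. The donor of the leading junction of the cluster was shared by 325 of 645 (50.4%, exact 95% binomial interval 46.5% to 54.3%), against 30.9% of 50875 rare junctions that were not raised (Fisher's exact test, two-sided, adjusted p = 1.5e-23). The acceptor of the leading junction was shared by 28.1% (24.6% to 31.7%), against 32.4% (adjusted p = 0.023). Among the 474 unannotated raised junctions, 57.6% joined an annotated donor to an unannotated acceptor, against 37.7% of unannotated rare junctions not raised (adjusted p = 1.1e-17). Intervals cover counting error only, and junctions of a gene are not independent. The junctions not raised were chosen by their pooled share and were not matched on the size of the cluster.

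Pairs of raised junctions delimited 70 exons that were rarely used in control. They lay in 65 annotated genes and had a median length of 64.5 bp (22 to 244 bp). Both junctions were annotated for 17 of them and neither for 47. Mean inclusion reached at most 3.13% in control and ranged from 6.48% to 55.2% in cKO. The genes in this paragraph were chosen after their values were seen. In Cttnbp2, which encodes a cortactin-binding protein, a 40 bp exon with both junctions annotated (chromosome 6, 18429120 to 18429159, minus strand) rose from 0.699% ± 1.2 to 55.2% ± 8.4 inclusion (SD, n = 3). In Ide, the insulin-degrading enzyme (chromosome 19, 37317508 to 37317546), an unannotated 39 bp exon rose from 0 reads to 35.8% ± 10. In Mapt, which encodes tau, an annotated 54 bp exon (chromosome 11, 104307881 to 104307934) rose from 1.52% ± 1.0 to 17.8% ± 5.5, and in Cltc, the clathrin heavy chain gene (chromosome 11, 86696176 to 86696213), a 38 bp exon rose from 0.500% ± 0.44 to 13.5% ± 0.58. In Cetn3, a centrin gene (chromosome 13, 81796150 to 81796177), a 28 bp exon rose from 0.859% ± 0.85 to 32.5% ± 7.1. Neither junction was annotated for the exons in Cltc and Cetn3. Each exon rests on 2 junctions that passed the edgeR junction test.

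**Figure D3:**
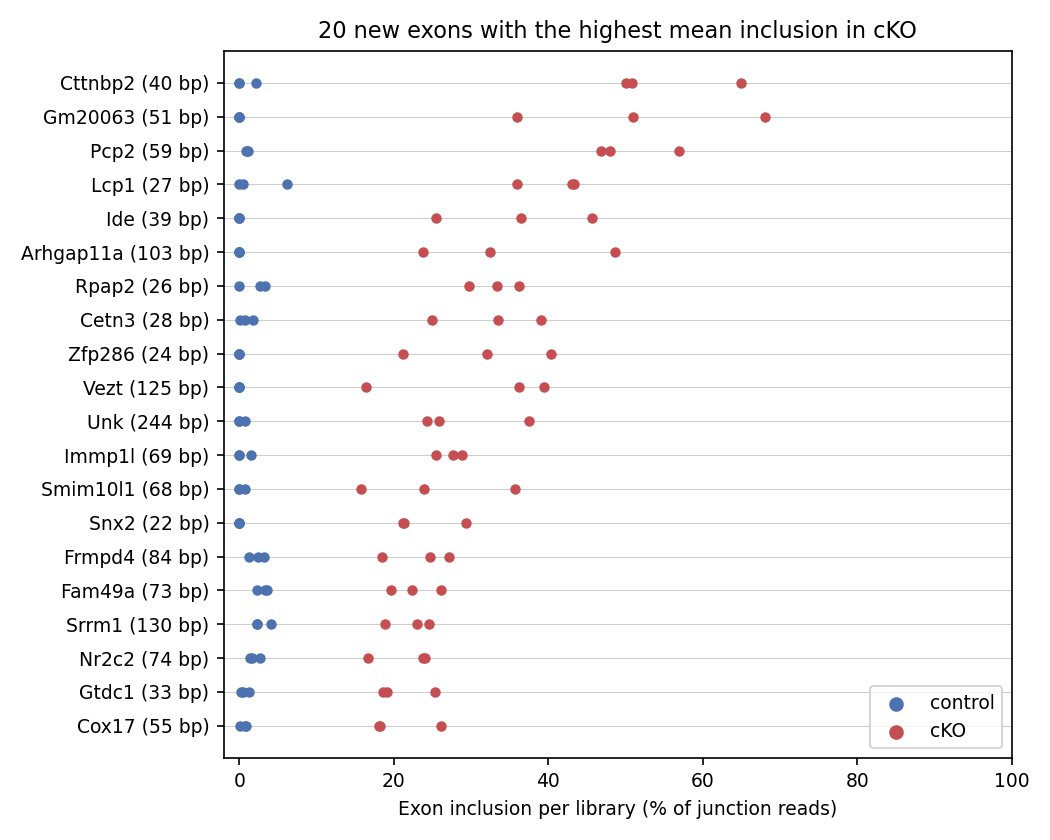
Inclusion per library (horizontal axis, percent of junction reads) of the 20 new exons, annotated or not, with the highest mean inclusion in cKO. Each point is 1 library and the exon length is given beside the gene. Control libraries lie at 6.19% (Lcp1) or below, and Cttnbp2 reaches a mean of 55.2% in cKO.

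In the Purkinje gene Pcp2, an exon rarely used in control reached about equal use with its skipping in cKO. This 59 bp annotated cassette exon (chromosome 8, 3623696 to 3623754, minus strand) rose from 0.99% ± 0.12 to 50.5% ± 5.5 inclusion (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). The junction that skips it (3623559 to 3624507) had 111522, 119047 and 114516 reads in control and 20212, 27973 and 33124 in cKO. Pcp2 was singled out here after its values were seen. The upstream constitutive junction (3624633 to 3624785) stood at 2125 ± 50 RPM in control and 863 ± 145 in cKO (SD, n = 3). The Pcp2-Cre transgene was present only in cKO.

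Raised rare junctions also lay in genes of the fixed lists. Among 31 Purkinje cell markers with a tested junction, 6 held one, among them Rgs8, Slc1a6 and Stac, and 6 of 36 receptor and scaffold genes did, among them Dlg2, Gria1 and Gria3. The count was 0 of 20 granule cell, 0 of 15 oligodendrocyte and 0 of 13 astrocyte markers. It was also 0 of 12 interneuron, 0 of 7 microglial and 0 of 5 endothelial markers. Of all genes with a tested junction and a gene test, 460 held one and 10290 did not. Whether the shares differ between lists or from those of other genes was not tested. In Stac the largest share rose from 0.0741% ± 0.13 to 17.7% ± 4.4 and in Gria3 from 0.0756% ± 0.13 to 12.8% ± 4.2 (SD, n = 3 each). In Tardbp, which encodes TDP-43, an annotated intron (chromosome 4, 148617738 to 148618664) rose from 0.0807% ± 0.14 to 7.71% ± 1.2. These genes were named after their values were seen.

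Unannotated junctions took 1.73% ± 0.23 of junction reads in control and 2.07% ± 0.053 in cKO (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow). After thinning each library to the junction reads of the smallest one, 56386 ± 1022 distinct unannotated junctions were seen in control and 81914 ± 6307 in cKO, 1.45 times as many (exact permutation p = 0.1). Distinct annotated junctions numbered 162555 ± 1625 and 167437 ± 2242, 1.03 times as many (SD, n = 3). Every cKO library exceeded every control library in all 3 measures.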

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

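The removal of Rn45s and Lars2, the thinning of junction reads, the narrower sets of rare junctions, and leaving out libraries or adding a block for the type of raised junctions were chosen after seeing the data. Rbm17 stayed called under each alternative run, with log2 fold changes of -0.71 to -0.68 when 1 library was left out. The count of 1265 called genes became 2107 with DESeq2 and 530 to 1037 with 1 library left out, where fewer samples enter the fit. The 13 called lists became 0 with an estimated correlation and 12 to 16 with 1 library left out. Between 14 and 24 of the named genes lost their call in each fit that left out a library, and at most 5 under any other alternative. Of the called ones 0 changed sign, and sign changes of named genes uncalled in both fits were not counted.

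With a share change of at least 10 points, 436 junctions were called, 294 rare junctions rose and 17 fell, as a stricter threshold requires. With reads that share the acceptor only, the counts were 556, 394 and 17, and the cause was not tested. With limma-voom, 2190 junctions were called, 1148 upward and 1042 downward, and 93 rare junctions fell against 838 that rose; the cause was not tested. Lowered rare junctions numbered 19 with rare set under 1% and 28 among unannotated junctions, as narrower sets require. With 1 library left out, 563 to 772 junctions were called, 429 to 600 rare junctions rose and 32 to 49 fell. The share of raised rare junctions that keep the main donor was 55.4% with rare set under 1%, 57.6% on annotated splice sites in unannotated junctions, and 49.2% to 55.7% with 1 library left out. The difference in unannotated read share ranged from 0.232 to 0.464 percentage points, and the ratio of distinct unannotated junctions from 1.39 to 1.49, with 1 library left out. Reads sharing the donor only gave a value for 14 of the 15 named junctions and reads sharing the acceptor only for 2, and the filter of 50 counts for 77 of the named genes; the others have no value there.

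Replicate numbers are shared between the groups, but deviations of same-numbered libraries correlated at only 0.045, -0.062 and 0.021, so the numbers were not taken to pair the libraries. With the replicate block 1734 genes and 777 junctions were called, 560 rare junctions rose and 42 fell, and 7 of the 15 named junctions lost their call. In the simulated data, with 200 genes changed, most changes of 1.5-fold were missed. The data called 1265 genes, and the adjusted threshold depends on how many genes change. The share missed therefore reflects that setting as well as depth and 3 libraries, and may differ in these data.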

Other observations

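The tests of chance, depth, the Pcp2 transgene and the share of Purkinje RNA were chosen after the results were seen. Host genes of raised rare junctions changed in both directions at gene level: of 460 host genes with a gene test, 11.5% fell and 8.48% rose, against 4.97% and 3.90% of 10290 other genes with a tested junction. These other genes were not matched to the hosts on expression, on which the share of called genes also depends. Among hosts of new exons, 8 of 64 fell and 4 rose. New exons had a length that is a multiple of 3 in 33 of 70 cases (47.1%, exact 95% binomial interval 35.1% to 59.4%). Hosts of exons whose length is not a multiple of 3 had a mean log2 fold change of -0.02 and the others one of -0.03. The difference was 0.01 (bootstrap interval reaching both signs, permutation p = 0.924). Whether the exons lie in coding sequence was not checked, so whether frame goes with host level stays open. Within 10 Mb of Rbm17, 4 of 79 genes were called (5.06%, exact interval 1.40% to 12.5%), against 7.78% elsewhere (Fisher's exact p = 0.525). The interval spans the value elsewhere, so an effect of flanking DNA carried with the null allele is neither shown nor excluded.

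The 3 against 3 libraries give 10 splits, too few for a share under 0.05. The real split called 1265 genes, 842 junctions and 645 raised rare junctions, and 1 of the 10 splits gave as many of each. The highest of the other splits gave 0 genes (up to 1412 at an unadjusted p under 0.05), 8 junctions and 7 rare junctions. Each other split mixes control and cKO libraries in both groups. A genotype difference would widen the spread within those groups and lower their calls, so these counts are not those of unaffected libraries. For the gene lists, 3 of the 10 splits gave as many called lists as the 13 of the real one, and the highest of the others gave 15.

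Rare junctions rose in 645 cases and fell in 44, and depth is argued against as the whole cause, since 645 still rose and 45 fell after thinning to equal junction reads. A fall of the host genes and RNA of other cell types were weighed by the level of the hosts. Their median log2 fold change was -0.0174 (interval -0.045 to 0.011). It stood at percentile 92.3 of 10000 lists matched on expression, whose median was -0.0352. This argues against a fall of the hosts as a set. Added transcripts would need a median rise of 0.14, and at the least 0.074, if the existing transcripts of the hosts kept their level. The interval lies below both. On that condition, which was not tested, this argues against transcripts added to the hosts alone, as a set. The members' quartiles of -0.21 and 0.21 leave single hosts open. The bounds stated before for the median took no account of that spread. TMM scaling would hide a general rise, so RNA of other cell types that raises most genes stays open. Of the hosts, 11.5% fell and 8.48% rose, shares whose difference from those of other genes, not matched on expression, was not tested. Long introns stay open: the leading introns were 1.16 times as long at the median as those of rare junctions not called (interval 1.01 to 1.29, permutation p = 0.018), and 1.12 times as long as a set matched on reads (p = 0.2, a comparison outside the stated prediction and run before the unmatched one). Markers of other cell types held 0 raised rare junctions, as given above, but these are few genes and the difference was not tested. Loss of RBM17 in Purkinje cells, the null allele in other cells and Cre differ together between the groups and stay open as untested.

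In Pcp2 the skipping junction stood 4.46-fold higher in control than in cKO, and the junction into the cassette exon 21.8-fold higher in cKO, in RPM of junction reads. Transcripts added by the Pcp2-Cre transgene would not by themselves lower the skipping reads, but the upstream constitutive junction also stood 2.46-fold higher in control. A lower endogenous level together with inclusion reads from the transgene could give the same values as a change in splicing. These cannot be told apart, since the transgene was present only in cKO.

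In the same libraries 11 of 20 microglial markers rose and 13 of 31 Purkinje markers fell (adjusted p = 0.47 for each list with an estimated correlation). A lower share of Purkinje RNA would raise all other cell types alike, yet markers of 5 other types had a median log2 fold change of -0.12 (quartiles -0.29 to 0.04), against 1.31 for microglia, which argues against it for the microglial rise. For the Purkinje fall the same value, -0.12, decides nothing, because TMM scaling centres most genes near 0 and so would hide a general rise. A change in microglia, or in what they add to the pull-down, was not tested.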
